A study of Mus musculus with 6 samples.

How the data were processed

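Gene expression was measured on 6 one-colour Affymetrix arrays, 1 for each of 3 mouse leukemia lines under each of 2 treatments. Per the labels' protocols, total RNA was extracted with Trizol from sorted GFP-positive leukemia cells, and 200 ng of it was labelled with biotin by the Ambion WT kit. The deposited values are probe set intensities on a linear scale. They were made with Affymetrix Expression Console 1.1 and RMA, per the submitters' processing notes, which name no other setting. RMA subtracts background, makes the distribution of probe intensities equal across arrays and combines the probes of a set. It therefore removes any difference in the overall signal between arrays. The linear scale was read from the values, since the median intensity lay between 202 and 208 and the maximum between 22658 and 24381 on each array. Array data have no read depth, and the number of arrays limits the precision.

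The table held 35556 probe sets. The platform annotation used here gave 1 gene symbol for 21789 of them and several symbols for 1621, and 12146 were unnamed here. Symbols were looked up by Entrez identifier in a table of RefSeq genes, where 21698 of the probe sets with 1 symbol were found and no symbol changed. The other 91 kept the annotation's symbol. Probe sets with several symbols or none were left out of the comparisons. For the 999 genes with several probe sets, the probe set with the highest mean over the 6 arrays was used, which left 19938 genes. The log2 of each intensity was taken. Genes whose mean was at or above the 30th percentile of genes, a log2 intensity of 6.70, were tested, and these numbered 13956. All values called log2 below were computed here from the deposited intensities.

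Treatments were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default arguments), with line and treatment as terms, so that line was a block. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and genes past an adjusted p of 0.05 were called changed. Each gene had 2 residual degrees of freedom, to which the moderation added 3.47. The block was chosen because the series design states that cells of each line went to recipients of both treatments. In the arrays, deviations from the group means correlated at 0.64, 0.68 and 0.68 between the arrays of the same line. The highest correlation of a Vehicle array with a Tamoxifen array of another line was -0.13. Deviations sum to 0 within a group, so positive values within lines push those between lines below 0. The value of -0.13 thus adds no support of its own. The fit without the block was run as an alternative. Differences between lines were tested with the moderated F test of the line terms in the same fit. Agreement among lines was described by correlations, across genes, of the within-line difference between treatments.

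Before the data were examined, 32 gene lists were fixed from general knowledge, together with the tests, the alternatives and the rule for naming genes. The lists held 561 genes, of which 434 were tested, 70 were too dim, 20 lay only on probe sets with several symbols and 37 were not named in the annotation used here. Lists with at least 3 tested genes, 31 of the 32, were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera draws on the 2 residual degrees of freedom, so it has little power here. A list of reported Zfx targets held Ptpmt1 and Idh2, which as far as is known this study itself put forward, so that list is not independent evidence. Another 8 lists were written after the changed genes had been read and were adjusted among themselves. Before that, 96 symbol roots with at least 15 tested genes each were searched for an excess of changed genes by one-sided Fisher tests, and 0 passed an adjusted p of 0.05, so p-values adjusted over the 8 lists understate the search.

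The rule for naming genes took, in each direction, the 10 changed genes with the largest log2 difference that moved the same way in all 3 lines. It always took Zfx, Ptpmt1, Idh2, Zfy1, Zfy2, Cdkn1a, Mdm2, Myc, Notch1, Hes1, Cd4, Cd8a and Kit. From each fixed list it took up to 4 changed members, or else the 2 with the smallest p, given as values. For the lines it took the 5 genes with the smallest p and, per line, the 3 changed genes farthest above the mean of the other lines. Members of the 8 later lists are named after their values were seen.

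The steps were tested on data simulated from the fitted levels and spreads of the 13956 genes. With 200 genes changed between treatments, 68% of those changed by 0.3 and 100% of those changed by 0.5, 1 or 2 on the log2 scale were called, in either direction. Over 20 simulations with 870 changed genes, a mean of 5.5% of the calls were false. With 200 changed genes it was 9.8%, above the 5% aimed at. With no gene changed, 9 of 20 simulations gave a call, with a mean of 0.9 calls. The gene list step recovered 2 of 2 shifted lists and called 1 list that had not been shifted. Genes were simulated with independent noise. In the data the estimated correlations of the 2 shifted lists were 0.45 for oxidative phosphorylation and 0.74 for mitosis. The simulation therefore does not test the list step for correlated genes. The line step called 100% of the genes made to differ by 1 or 2, with 28 false calls.

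The alternatives were no filter on dim genes, a filter at the 50th percentile, quantile normalization applied again, arrays centred on their median, the mean of all probe sets of a gene, eBayes with trend and robust settings, arrayWeights, an adjusted p under 0.10, a 2-fold minimum, and each line left out in turn. Cyclic loess between arrays and a fit of all probe sets together were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.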

Results

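The study asked how gene expression in Notch-driven T cell acute lymphoblastic leukemia (T-ALL) differs after the gene for the zinc finger transcription factor Zfx is deleted. Leukemias had been made by introducing the active intracellular part of Notch into mouse blood progenitors that carried a loxP-flanked Zfx allele and a Cre recombinase activated by tamoxifen. The 3 independent leukemias, lines 14843, 14844 and 14846, were passed to secondary recipient mice. From day 10 after transplant, recipients received Vehicle or 5 mg of Tamoxifen a day for 3 days, and GFP-positive leukemia cells were sorted 48 h after the last dose. Each line gave 1 Vehicle and 1 Tamoxifen array, so each group held 3 arrays from separate leukemias. The design included no Tamoxifen group without Cre or without the loxP-flanked allele, so effects of the drug, of Cre activity and of any loss of Zfx cannot be separated. Correlations between arrays over all probe sets lay between 0.991 and 0.996.

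The Zfx probe set did not differ between the groups. Its level was 10.87 ± 0.14 log2 intensity in Vehicle arrays and 10.94 ± 0.06 in Tamoxifen arrays (SD, n = 3 each). The fitted difference was 0.07 ± 0.06 (SE), with a limma adjusted p of 0.48, and the within-line differences were -0.01, 0.08 and 0.15 in lines 14843, 14844 and 14846. The table held 1 probe set for Zfx, and the positions of its probes and the deleted part of the gene are not given in the sources used here. A probe set outside the deleted part would not respond to the deletion, so this value does not check the labels, and groups are named below as the arrays are labelled. The relatives Zfy1 and Zfy2 were below the filter on dim genes, at log2 differences of -0.01 ± 0.05 and -0.04 ± 0.06 (SE).

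**Figure D1:**
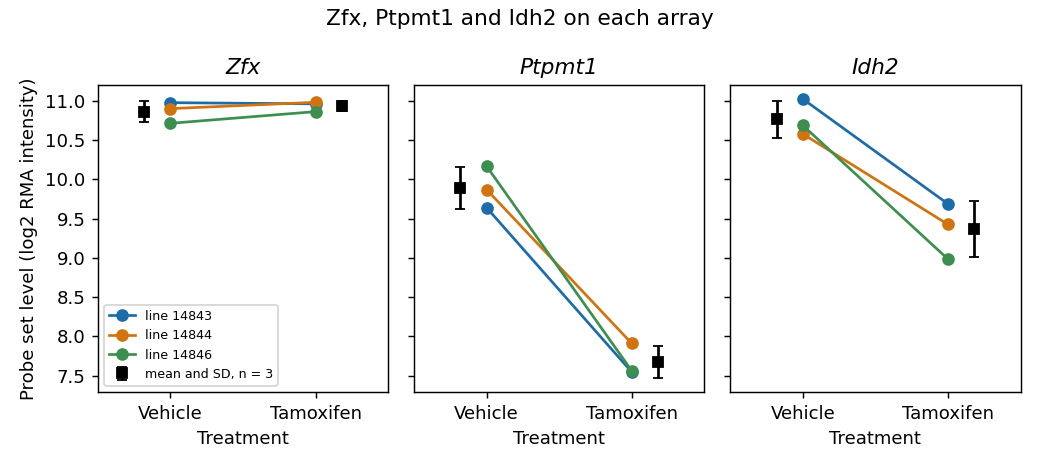
Level of the Zfx, Ptpmt1 and Idh2 probe sets (log2 RMA intensity) on each of the 6 arrays, with lines joining the Vehicle and Tamoxifen arrays of the same leukemia and squares giving the group mean and SD (n = 3). Zfx lies between 10.72 and 10.98 on all arrays, while Ptpmt1 and Idh2 are lower in the Tamoxifen array of each line.

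Ptpmt1 and Idh2, genes reported as Zfx targets, were lower in arrays labelled Tamoxifen. Ptpmt1, a mitochondrial phosphatase of cardiolipin synthesis, fell from 9.89 ± 0.26 to 7.67 ± 0.21 log2 intensity (SD, n = 3 each), a 4.66-fold decrease with a limma adjusted p of 0.0027. Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase, fell from 10.77 ± 0.23 to 9.37 ± 0.36, a 2.64-fold decrease with an adjusted p of 0.0063. Both were lower in each of the 3 lines, with log2 differences from -2.61 to -1.96 for Ptpmt1 and from -1.70 to -1.15 for Idh2. The list of reported targets had 3 tested genes, of which 2 fell, and also 2 when adjusted over the list alone. The list as a whole had a camera adjusted p of 0.063, and 0.94 with an estimated correlation, and passed under 7 of 11 other settings of the gene-level analysis. As far as is known this study itself put forward these genes, so the list is not independent evidence of a direction.

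Among changed genes, arrays labelled Tamoxifen held more decreases than increases. Of 13956 genes, 870 changed, 688 lower and 182 higher, while the median log2 difference over all 13956 was 0.03. Without line as a block 295 changed, 275 lower and 20 higher, and these 295 were among the 870. Lower genes made up 79.1% of the calls, but 57.7% after each array was centred on its median, where 562 were lower and 412 higher. Centring raised the median log2 difference over all 13956 genes from 0.03 to 0.08. Changes of at least 2-fold numbered 57 lower and 3 higher. The median difference was -0.48 among lower genes and 0.37 among higher genes on the log2 scale. Values of the groups did not overlap for 3306 of the 13956 tested genes and for 755 of the 870 changed genes. Chance gives 10% for exchangeable arrays, but these arrays are paired by line, so that rate is no test here. The changed genes had already been selected for a difference. The number of calls was lowest without line 14844: it was 70 without that line, 498 without line 14843 and 669 without line 14846. Each of these fits had fewer residual degrees of freedom than the full fit. All 870 genes moved the same way in each of the 3 lines. They therefore had to keep their direction whichever line was left out. Lines 14843 and 14846, left when line 14844 is dropped, had the lowest correlation of treatment differences, 0.49. Line 14844 itself had the fewest genes at least 2-fold lower, 47 against 98 and 103 in lines 14843 and 14846. The lower count thus does not show that the changes came from line 14844.

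The 10 largest decreases exceeded 2-fold. Cibar1, a BAR domain protein linked to cilia, fell 6.79-fold, with a log2 difference of -2.76 ± 0.08 (SE). Lpgat1, a lysophosphatidylglycerol acyltransferase, differed by -2.23 ± 0.15. Dis3l, an RNA exosome nuclease, differed by -2.08 ± 0.06, and Npepl1, an aminopeptidase-like protein, by -2.03 ± 0.05. Rcn2, a calcium-binding protein of the endoplasmic reticulum, and Nckap1, a subunit of the actin-regulating WAVE complex, differed by -1.85 ± 0.10 and -1.81 ± 0.10. With Ptpmt1, the list of 10 was completed by Lrrc41 at -1.64 ± 0.05, Ankrd52, a regulatory subunit of protein phosphatase 6, at -1.55 ± 0.05, and the zinc finger gene Zfp354c at -1.54 ± 0.08. All 10 also passed without the block, at adjusted p-values from 8.1e-04 to 0.0092, and without line 14844 Lpgat1 alone of the 10 missed the threshold, at an adjusted p of 0.0502.

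The largest increases were smaller. Cym, the protease chymosin, rose 2.51-fold, with a log2 difference of 1.33 ± 0.11 (SE), and Lgi1, a secreted leucine-rich repeat protein, by 1.24 ± 0.13. Cd80, a ligand of the T cell costimulatory receptor CD28, rose by 1.07 ± 0.14 on the probe set used, while its other probe set, of nearly the same mean level, gave 0.25 ± 0.09. Gramd3 rose by 0.92 ± 0.12, the calcium-binding S100a1 by 0.86 ± 0.16 and Ccdc125 by 0.75 ± 0.12. Mapk11, a p38 kinase, the glycogen branching enzyme Gbe1, the sialyltransferase St6gal1 and the peroxisomal enzyme Phyh rose by 0.71 to 0.72. None of these 10 passed without the block, at adjusted p-values from 0.074 to 0.39. Without line 14844, 7 of them missed the threshold, namely Cd80, S100a1, Ccdc125, Mapk11, Gbe1, St6gal1 and Phyh.

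**Figure D2:**
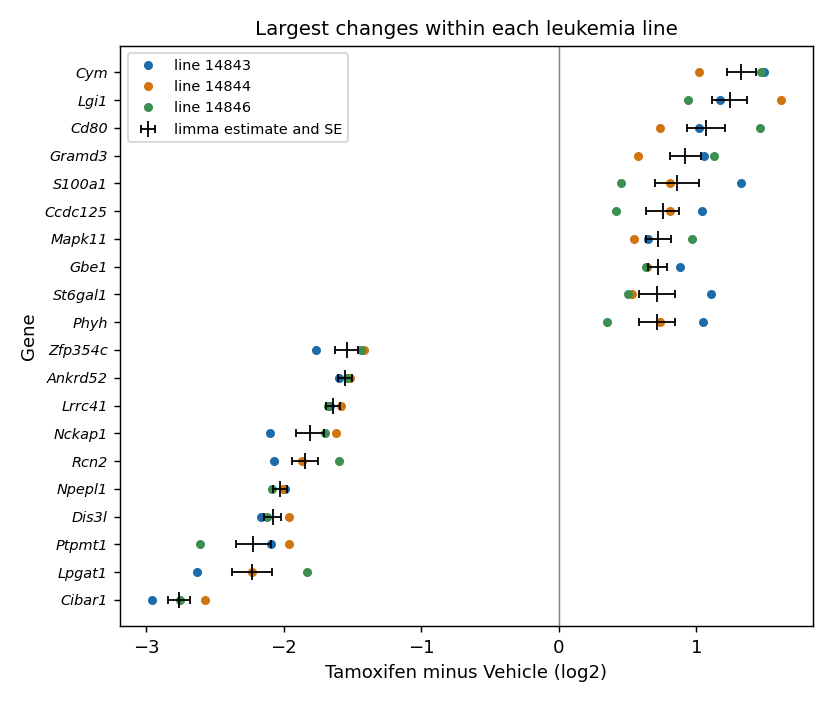
Difference between Tamoxifen and Vehicle arrays (log2) for the 10 largest decreases and the 10 largest increases. Dots are the difference within each line, and black bars are the limma estimate with its standard error. Estimates run from Cibar1 at -2.76 to Cym at 1.33, and the rule that chose the 20 genes required the 3 dots to lie on the same side of 0.

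The fixed gene lists asked whether pathways of T-ALL or markers of other cells moved as groups. None of 31 lists passed camera's adjusted p of 0.05 at the preset correlation, while 6 had an unadjusted p under 0.05. With an estimated correlation and with fry's directional test, 0 lists passed, with adjusted p-values from 0.94 to 0.99 and from 0.59 to 0.95. The smallest unadjusted p of camera with an estimated correlation was 0.22. With few residual degrees of freedom that test could hardly pass a list, so its misses decide little. For the 6 lists with an unadjusted p under 0.05, the estimated correlations were 0.22 to 0.85, above the preset 0.01. They rest on few degrees of freedom, but if they hold, camera's p-values at the preset correlation are too small. Fry's mixed test, which asks whether members change in either direction, passed 15 lists. Over all lists, 14 of 434 tested members changed, 8 lower and 6 higher. Over all genes it was 870 of 13956, 688 lower and 182 higher. The lists thus held a smaller share of changed genes than the tested genes as a whole, and single changed members below are to be read against that share.

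The chaperone list came closest to the threshold. Among 10 tested heat shock genes the median log2 difference was -0.17, with a camera adjusted p of 0.051, and 0.94 with an estimated correlation. It passed under 8 of 12 other settings of the gene-level analysis. Of these, Bag3, a co-chaperone of Hsp70, fell 1.99-fold, with an adjusted p of 0.0040, but of 0.073 without the block, which ends the call, and 1 gene fell also when adjusted over the list alone. Among 16 genes of the unfolded protein response, Sdf2l1 and Creld2, both of the endoplasmic reticulum, rose by 0.52 ± 0.10 and 0.30 ± 0.05. Adjusted over the list alone, 2 were higher and 1 lower, and the list's adjusted p was 0.66. Creld2 lost its call whichever line was left out, and Sdf2l1 lost it without line 14843 or 14844, and without the block both lost it, at adjusted p-values of 0.054 and 0.076.

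Metabolic lists held single changes in opposite directions. Idh2 and Ptpmt1, both lower, had been placed only in the list of reported Zfx targets. The citric acid cycle list therefore lacks Idh2, and the mitochondrial phospholipid list lacks Ptpmt1. In the citric acid cycle list, of 19 tested genes, Aco1 fell, at -0.52 ± 0.08 (SE), and Idh1 rose by 0.35 ± 0.07, and the same 1 lower and 1 higher passed when adjusted over the list alone. Both encode cytosolic enzymes, an aconitase that also binds iron-responsive RNA elements and an isocitrate dehydrogenase. Of 26 oxidative phosphorylation genes, Ndufv1, a subunit of complex I, rose by 0.28 ± 0.05, and 0 passed when adjusted over the list alone. The adjusted p-values of these lists were 0.79 and 0.65. Ndufv1 lost its call whichever line was left out, and Aco1 and Idh1 lost theirs without line 14843 or 14844. Without the block all 3 lost their calls, at adjusted p-values of 0.15 for Ndufv1, 0.093 for Aco1 and 0.34 for Idh1.

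Cell death lists held 1 change each. Among 17 p53 targets, Ei24, a protein of the endoplasmic reticulum induced by p53, fell, at -0.95 ± 0.12 (SE), and adjusted over the list alone 2 were lower, with a list adjusted p of 0.65. Among 17 apoptosis regulators, Apaf1, the core of the apoptosome, rose by 0.33 ± 0.05, with 1 also when adjusted over the list alone and a list adjusted p of 0.92. The p53 regulator Mdm2 gave 0.06 ± 0.05. Cdkn1a lay only on a probe set with several symbols and is not reported. Of 7 replication-dependent histone genes, H2bc4 and H1f2 fell, at -1.52 ± 0.22 and -0.37 ± 0.05, with 2 lower also when adjusted over the list alone and a list adjusted p of 0.61. Ei24 and H2bc4 lost their calls without line 14844, and Apaf1 and H1f2 lost theirs whichever line was left out. Without the block Ei24, Apaf1 and H1f2 lost their calls, at adjusted p-values of 0.28, 0.065 and 0.41.

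Lists of leukemia identity had no changed member. Among 17 Notch targets 0 changed, also when adjusted over the list alone, with a median of -0.10 and a list adjusted p of 0.12. Notch3, Ptcra, Notch1 and Hes1 gave -0.46 ± 0.12, -0.27 ± 0.08, -0.11 ± 0.05 and -0.09 ± 0.15 (SE), and Myc gave -0.20 ± 0.09. Of 21 thymocyte maturation genes Rag2 gave -0.75 ± 0.16 and Bcl2 0.33 ± 0.07, neither past the threshold, and the surface markers Cd4 and Cd8a gave -0.08 ± 0.21 and -0.09 ± 0.12. The signs of Hes1, Cd4 and Cd8a differed between lines. Kit was below the filter, at 0.03 ± 0.04.

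Markers of other cells that a GFP sort could leave in showed 2 changes. Of 10 tested monocyte and macrophage markers, Hmox1, an enzyme of heme breakdown that many cell types induce, rose by 0.43 ± 0.06 (SE), as did 1 when adjusted over the list alone, with a list median of 0.10 and adjusted p of 0.12. Of 8 NK and cytotoxic cell markers, Tbx21, a transcription factor that T cells also express, fell, at -0.26 ± 0.05, with 1 lower also when adjusted over the list alone and a list adjusted p of 0.88. Hmox1 lost its call without line 14843 or 14844, and Tbx21 lost it whichever line was left out and after arrays were centred on their median. Without the block both lost their calls, at adjusted p-values of 0.15 and 0.37.

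Changes were absent or were called only within a list for the remaining lists. Of 13 interferon response genes 0 changed, and adjusted over the list alone 2 were higher and 2 lower, with a list adjusted p of 0.65. Of 9 estrogen receptor targets 0 changed, and adjusted over the list alone 1 was higher and 1 lower, with an adjusted p of 0.65. In 19 lists 0 genes changed over all genes or when adjusted over the list alone, and their adjusted p-values lay between 0.10 and 0.99. Besides Notch targets and thymocyte maturation, these covered early T progenitors, T cell receptor signalling, DNA replication and mitosis. Mitochondrial phospholipid synthesis, a list without Ptpmt1, was also among them, as were glycolysis, cholesterol synthesis, ATF4 targets and immediate early genes. The 19 lists also covered Myc targets, ribosomal proteins, glucocorticoid targets, erythroid cells, neutrophils, B cells, stroma and hepatocytes. Among them ATF4 targets, at a median of 0.14 and an adjusted p of 0.10, DNA replication, at 0.08 and 0.19, and Notch targets, at -0.10 and 0.12, had an unadjusted p under 0.05. In 7 lists the median, the mean and the test did not share a sign.

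Other members of these lists that the rule names gave values short of the threshold. Examples were Hsd17b7 of cholesterol synthesis at 0.68 ± 0.14 (SE), Igfbp4 of the estrogen receptor targets at 0.72 ± 0.16, Slc7a11 and Chac1 of the ATF4 targets at 0.50 ± 0.12 and 0.43 ± 0.12, and Egr1 of the immediate early genes at 0.42 ± 0.11. In DNA replication Rfc3 and Rfc4 gave 0.27 ± 0.06 and 0.25 ± 0.06. In the interferon list Bst2 and Irf9 gave -0.26 ± 0.05 and -0.31 ± 0.06, and among T cell receptor genes Cd2 gave -0.19 ± 0.05.

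**Figure D3:**
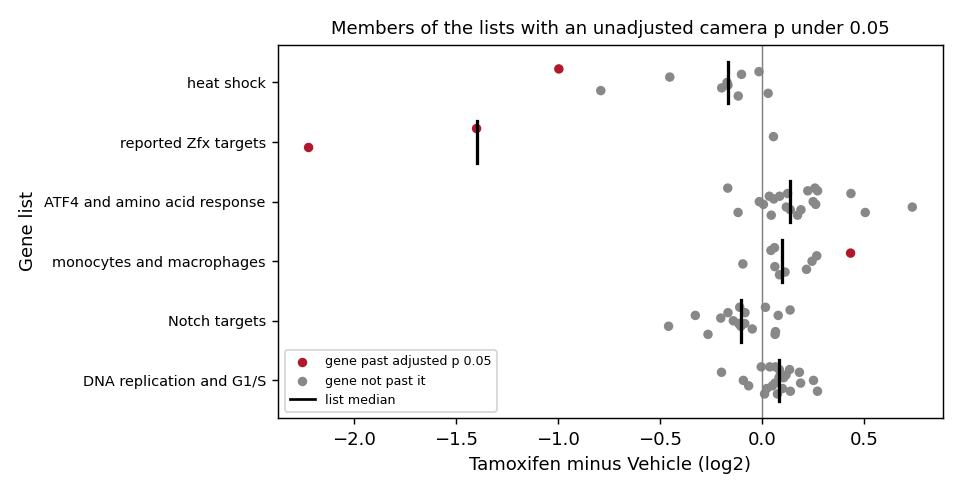
Difference between Tamoxifen and Vehicle arrays (log2) for each tested member of the 6 fixed lists with an unadjusted camera p under 0.05. Dots are genes, in red where past an adjusted p of 0.05, and black bars are list medians, from -1.40 for reported Zfx targets to 0.14 for ATF4 targets.

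The 3 leukemias differed from each other on average over the treatments. Between lines 434 genes differed by limma's moderated F test, 200 of them by at least 2-fold. Line accounted for 58.2% of the sum of squares over genes, treatment for 29.7% and the residual for 12.1%. These shares are not divided by degrees of freedom, of which line has more than treatment, so they do not rank line above treatment. Genes with the smallest p included the peptide transporter Slc15a2, at 6.11 ± 0.03 log2 intensity in line 14843 against 10.41 ± 0.10 and 10.36 ± 0.08 in lines 14844 and 14846 (SD, n = 2 arrays each). The coagulation inhibitor Tfpi was at 6.38 ± 0.02 in line 14844 against 9.42 ± 0.02 and 10.24 ± 0.00, and Cpsf4l, Hormad2 and Stxbp6 spanned 3.15, 2.71 and 2.19 log2 units between lines. Line 14843 stood farthest above the mean of the other lines for Hormad2, Ctnnd1 and Gm10384, by 2.60, 2.55 and 2.26. Line 14844 did so for Scara3, Fgf13 and E330013P04Rik, by 2.43, 2.36 and 2.20, and line 14846 for Gdpd3, Ly86 and S100a10, by 4.02, 3.78 and 3.54. Some of these genes also differed widely between the 2 arrays of line 14846, with an SD of 1.63 for Ly86, 1.17 for E330013P04Rik and 1.05 for Fgf13. E330013P04Rik was at 10.48 in line 14844 and 9.99 in line 14846, against 6.57 in line 14843. It was thus low in line 14843 rather than high in line 14844 alone. Fgf13 lost its call under eBayes with trend and robust settings, and Ly86 lost it under those settings and without the filter on dim genes. Of the fixed list members, 15 differed between lines, all named here outside the naming rule. These were Gata3 and Tspan6 of the Notch targets, S1pr1 of thymocyte maturation, Slc7a11 of the ATF4 targets, the histone gene H1f2, and markers of other cells, namely Lcn2, Ngp and S100a8 of neutrophils, Lyz2 of monocytes and macrophages, Cd74 and H2-Aa of B cells, Klrb1c and Nkg7 of NK cells, and Col1a2 and Eng of stroma. In total 76 genes passed both the line and the treatment test, which share the residual of each gene and so are not independent.

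Within-line differences between treatments were related across lines. Across the 13956 genes, which are not independent replicates, Pearson's r was 0.67 between lines 14843 and 14844, 0.49 between 14843 and 14846 and 0.58 between 14844 and 14846. Spearman's rho was 0.51, 0.39 and 0.42. Of all tested genes 48.8% moved the same way in the 3 lines, where chance gives 25%. The number of genes at least 2-fold lower was 98, 47 and 103 in lines 14843, 14844 and 14846, and at least 2-fold higher 57, 3 and 6. Each line had 1 array per treatment, so a response of a single line has no test.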

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

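The fit of all probe sets together, cyclic loess, the classes of mean level and the tests on other cell types, on exchanged labels, on probe positions and on changes of at least 2-fold were chosen after the result was seen. Probe sets that the comparisons leave out held a few increases in arrays labelled Tamoxifen. When all probe sets were fitted together, 3 of 7667 with no gene named here were higher than in Vehicle arrays and 33 were lower. Among 981 probe sets with several gene symbols, 1 was higher and 3 were lower. When each class was fitted alone, 0 were called higher in both classes, with 0 and 3 lower, so the calls of increases appear only in the joint fit. The log2 differences are the same in either fit. The largest called increases were 0.52 ± 0.05 for probe sets with no gene named here and 0.98 ± 0.10 for those with several symbols (SE, joint fit).

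Most changed genes were lower in arrays labelled Tamoxifen, 688 against 182. Over 3 equal classes of mean level, from lowest to highest, the share of lower genes was 68.6%, 78.7% and 83.0%. Decreases prevailed in each class, which argues against compression of only dim or only bright signals as the whole cause. A part played by level stays open, since the share rose with it. Cyclic loess left 78.4% lower and the fits without 1 line at least 74.7%, above a bound of 60%. That bound was set before loess was run but after the split of calls had been seen. The loess share argues against a trend with level left by the authors' normalization as the whole cause. The fits without 1 line used the same normalized values, so their shares do not bear on normalization. Among changes of at least 2-fold the lowest share over 3 normalizations was 91.8%. That share cannot decide about normalization, since RMA had already made the arrays alike and median centring added only 0.0592 to each difference. A shift of all genes alike stays open, since RMA would hide one. Centring arrays on their median gave 57.7%, but it added 0.0592 to every fitted difference, which by itself moves that share. It also shifted the lines by unequal amounts, which changes the residuals, and 727 of its 974 calls were shared with the main fit. Loss of other cells stays open too. The median of 0.0573 over 59 markers pools 7 cell types, and 35 of the markers lie within 1 log2 unit of the filter. A response to deletion of Zfx remains a hypothesis, since the drug and Cre activity were not separated from it.

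Of the 4 splits of the arrays that part all 3 pairs, 1, the real one, gave as many changed genes, 870 against at most 0 in the others, which exchange the labels of 1 or 2 lines. Without the block, 1 of 10 splits gave as many, 295 against at most 0. Both numbers of splits are too few for a share under 0.05.

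The Zfx probe set was not lower in arrays labelled Tamoxifen, at 0.07 ± 0.06 (SE). An exchange of labels within 1 line is argued against, because differences between treatments correlated at 0.49 or more between each pair of lines. An exchange in all 3 lines would leave that value as it is and was not tested. Probes outside the deleted part could give this value, but with 1 probe set and no positions this cannot be told apart from incomplete deletion.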

How the results depend on the processing

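Cyclic loess and the fit of all probe sets together were chosen after seeing the data, and the cause of each shift below was not tested unless stated. The Zfx difference stayed above 0 and short of the threshold under all settings run, between 0.03 and 0.13. The number of changed genes, 870, depended on the setting. Without line as a block (no replicate block) it was 295, with 20 higher and 275 lower. With an adjusted p under 0.10 it was 1643 (502 higher, 1141 lower), and with a 2-fold minimum 60 (3 higher, 57 lower), both by construction. All probe sets in one fit gave 196 (17 higher, 179 lower) among those with 1 symbol. Centring arrays on their median gave 974, with 412 higher. Leaving out 1 line gave 70 to 669 changed genes, 3 to 169 higher and 67 to 500 lower. The other settings gave 792 to 942.

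Of 33 named genes that changed, 21 lost the call without the block, 19 when some line was left out and 5 under another setting, and 0 reversed. Of the named genes short of the threshold, 4 reversed under some setting and 13 gained a call, namely Rag2, Bcl2, Rfc3, Hk2, Slc2a3, Hsd17b7, Slc7a11, Bst2, Irf9, Egr1, Egr2, Rrp9 and Igfbp4. With 1 line left out, Hes1 ranged from -0.210 to 0.154, Cd4 from -0.355 to 0.226, Cd8a from -0.185 to 0.0882 and Trf from -0.0790 to 0.638, and Cd4 gave 0.0035 with arrayWeights.

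Gene lists past the threshold numbered 0 in the main analysis. They numbered 2 without the block, 2 after quantile normalization and 2 after median centring, heat shock and reported Zfx targets each time. They numbered 1 without the filter, 1 with the mean of probe sets and 1 with arrayWeights, heat shock each time. After cyclic loess 4 passed, heat shock, reported Zfx targets, DNA replication and ATF4 targets. Without line 14843 only reported Zfx targets passed. Without line 14844 6 passed, reported Zfx targets, Notch targets, DNA replication, mitosis, ATF4 targets and monocytes, and without line 14846 4 passed, reported Zfx targets, cholesterol synthesis, ATF4 targets and heat shock. Of 12 alternatives of the gene-level analysis, heat shock passed under 8, at adjusted p-values from 1.2e-05 to 0.13, ATF4 targets under 3, DNA replication under 2 and Notch targets, mitosis, cholesterol synthesis and monocytes under 1 each. Genes differing between lines numbered 674 after median centring, 865 at an adjusted p under 0.10 and 200 with a 2-fold minimum, against 434, and 348 to 510 under the others. Of 13 genes named for lines, 2 lost the call, Fgf13 with trend and robust settings and Ly86 with those settings and without the filter. The mean correlation of treatment differences between lines, 0.58, was 0.0105 when genes past an unadjusted p of 0.05 were left out, a choice that by construction removes genes on which lines agree, and 0.55 to 0.61 otherwise. Signal over background limits dim genes, of which 5982 were not tested.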

Other observations

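All tests of this part except the count of splits were chosen after the result was seen, on 8 gene lists written after the changed genes had been read. A search of 96 symbol roots came before these lists, and 0 roots passed, with a smallest p of 0.0030 and a smallest adjusted p of 0.17, so p-values adjusted over the 8 lists understate the search. Of these lists 6 passed camera's adjusted p at the preset correlation, and 0 did with an estimated correlation, at adjusted p-values from 0.41 to 0.67. The latter test has little power here, so its misses below decide little. The estimated correlation was 0.18 for intraflagellar transport. It lay between 0.06 and 0.64, above the preset 0.01, in every list but the ciliary transition zone and basal body. If members are so correlated, camera's p-values at the preset correlation are too small. For the ciliary transition zone and basal body, at an estimated correlation of -0.03, camera's unadjusted p was 0.051, against 0.00017 at the preset one. Fry's directional test passed that list, intraflagellar transport and palmitoyl transferases, at adjusted p-values of 0.028, 0.045 and 0.037, and no other. Genes of cilia were among those lower in arrays labelled Tamoxifen, although lymphocytes lack a primary cilium. Of 28 intraflagellar transport genes 10 fell, among them Ift22 at -0.92 ± 0.05 (SE), Ift81 at -0.91 ± 0.10, Wdr34 at -0.87 ± 0.07 and Ift57 at -0.69 ± 0.06, with a list adjusted p of 4.4e-06, but 0.41 with an estimated correlation. Of 29 genes of the ciliary transition zone and basal body 6 fell, led by Iqcb1 at -1.46 ± 0.09, with an adjusted p of 0.00065, but 0.41 with an estimated correlation. Of 8 BBSome genes 1 fell, Bbs2 at -0.32 ± 0.06, with an adjusted p of 0.11.

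Of 34 autophagy genes 5 fell, among them Stx17 at -1.01 ± 0.06 (SE) and Ulk2 at -0.88 ± 0.06, with an adjusted p of 0.0071, but 0.41 with an estimated correlation. Of 20 antioxidant enzymes 7 fell, with Prdx2 at -1.08 ± 0.17 and Gclm at -0.63 ± 0.09, and Hmox1 rose, with an adjusted p of 0.0071, but 0.41 with an estimated correlation. Of 20 palmitoyl transferases 5 fell, with Zdhhc1 at -1.23 ± 0.13 and an adjusted p of 0.0083, but 0.41 with an estimated correlation. Of 18 cytosolic tRNA synthetases 2 rose, Lars by 0.46 ± 0.09 and Tars by 0.43 ± 0.06, with an adjusted p of 0.00065, but 0.49 with an estimated correlation, which was 0.64 for this list. Of 12 peroxisome biogenesis genes 2 fell, Pex5 at -0.47 ± 0.06 and Pex6 at -0.41 ± 0.05, and the list's adjusted p was 0.34.

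Of 10000 random lists matched on mean level to the intraflagellar transport genes, 95% had medians between -0.0374 and 0.0751, so genes at that level were not lower as a group by about that list's -0.23, which argues against a shift at that level of signal. Medians within lines were -0.22, -0.11 and -0.21 in lines 14843, 14844 and 14846, with upper 95% bootstrap bounds over genes of -0.0857, 0.02 and -0.0933, a criterion that replaced a first one, a median under -0.1 in each line, after its value had been seen. Whether 1 line alone carries the fall cannot be told, since the list was written after reading genes that had fallen and each line has 1 array per treatment. A hypothesis is that ciliary genes as a class may fall with deletion of Zfx. The test over 3 ciliary lists left it undecided, since the largest adjusted p was 0.110, and the drug alone was not tested.

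The 6 fixed lists with an unadjusted p under 0.05 were not more than other splits gave. All 4 splits that part the 3 pairs, the real one included, gave as many, with at most 10 in the others, and 4 splits are too few for a share under 0.05.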
